A study of Escherichia coli str. K-12 substr. MG1655 with 2 samples.

How the data were processed

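Total RNA of Escherichia coli K-12 MG1655 was profiled by directional RNA sequencing in 2 libraries, labelled replicate 1 and replicate 2, which form a single group. Per the labels' protocols, cells were grown in M9 minimal medium with 0.2% glucose at 30 °C to an optical density of about 0.6, RNA was taken by the RNAsnap method, ribosomal RNA was depleted with a Ribo-Zero kit, and fragmented RNA was made into libraries with a stranded TruSeq kit. The protocol text also describes a rifampicin treatment, but neither library carries a label for it, so no treated group was formed. Per the submitters' processing notes, CASAVA 1.4 was used. The aligner, the counting rule, the annotation and the way in which the 2 libraries were combined are not given in the sources used here. The kit keeps the strand, but whether the counting used it is not given either, so values of genes that overlap a gene on the other strand are uncertain. The same holds for near-identical copies such as tufA and tufB or gadA and gadB, whose reads the counting could split.

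The deposited gene table gave reads per kilobase and mapped library size (RPKM), as its header names the column, with 1 value for each of 4205 locus tags and none per replicate. The labels of both libraries name this same table, so each RPKM is treated as the authors' value for the pair. No standard deviation between replicates, no p-value across replicates and no replicate agreement can be computed from it, and a difference between 2 single genes has no replicate check. The table gives neither counts nor gene lengths, and the number of reads behind each RPKM was not estimated. The other deposited file was a coverage profile, with 1 scaled signal value per base and strand, the reverse strand carrying a minus sign. Its track names contain the word rpkm, but the values are scaled coverage per base rather than per kilobase.

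Depth was estimated from the profile. All 96 distinct values up to 4 lay within 0.0055 of a whole multiple of 0.0413, which was taken as 1 read. This step corresponds to scaling by about 24200000 reads. Of 8708 isolated stretches covered by 1 read, 60.5% were 51 bases long, and the summed coverage divided by the step and by 51 bases gave about 30300000 aligned reads for the pair. These 2 estimates of depth differ, and which of them counts the mapped reads is not given in the sources used here. The profile names its sequence NC_000913 without a version. The gene coordinates at hand belong to the assembly ASM584v2, and the build of the profile could not be settled, so the profile was not matched to genes and the planned antisense share per gene was not computed.

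Locus tags were paired with symbols through RefSeq's gene table for ASM584v2, which held 4651 locus tags. Of the 4205 tags, 4203 matched, 4136 of them protein-coding, 60 non-coding RNA, 6 pseudogenes and 1 of another type (ssrA), and 2 had no match. No matched tag was a tRNA or rRNA gene. Only names, gene types and the order of genes along the chromosome were taken from that table.

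Levels were analysed as log2(RPKM + 1). With a single condition and no control samples, the comparisons possible are between groups of genes within these libraries. Before the data were examined, 41 gene lists, 9 contrasts between lists, 26 operons and the rule for naming genes were fixed. The lists covered the translation and transcription machinery, the sigma factors and their regulons, biosynthesis and catabolism, respiration, the envelope, motility and stress, and together held 875 distinct protein-coding genes. An older symbol was accepted where it matched exactly 1 gene, and 1 matched list gene, the pseudogene gatC, was left out because the background was the protein-coding genes.

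For each list, the median log2 level was set against 10000 random lists of the same size drawn from all 4136 protein-coding genes (two-sided permutation test), with Benjamini-Hochberg adjustment over the 41 lists and a threshold of 0.05. The smallest unadjusted p this can give is 0.0002. Because neighbouring genes share transcripts (the correlation of log2 levels across adjacent protein-coding genes was 0.62), each list was also moved along the gene order through every offset, which keeps neighbours together; this is called rotation below. Contrasts between 2 lists used a two-sided permutation test of the difference of medians with 100000 resamples, or complete enumeration (an exact test) where a list held few genes, adjusted over the 9 contrasts; the smallest p that 100000 resamples can give is 1e-05. These p-values concern the genes of these libraries, not repeated cultures. Folds between lists are on the log2(RPKM + 1) scale and understate differences of low genes. For each operon, the last gene was compared with the first, and an exact two-sided sign test was run over operons.

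The list test was tested on simulated data made from the measured levels of 4136 genes. Among 100 lists of 20 genes it called 1 with no shift and 25 at a shift of 1 on the log2 scale. It called 64 at a shift of 2 and 90 at a shift of 3. Among 100 unshifted lists made of runs of 5 adjacent genes, it called 23, and rotation called 2. The contrast test called 45 of 50 simulated contrasts with a shift of 4 and 3 of 50 with none. Contrasts between lists made of runs of adjacent genes were not simulated. The rate of false calls for contrasts of lists that hold operon neighbours is therefore not known. The simulated calls were not part of the adjustment over the lists and contrasts reported here, so these rates need not hold for the adjusted calls.

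The genes named are the 15 of highest RPKM, the RNA polymerase core subunits and sigma factors, up to 2 members of highest and up to 2 of lowest RPKM in each list described, and the 3 steepest falls and rises among the operons. Exceptions are marked as chosen after their values were seen. Alternatives tried were pseudocounts of 0.1 and 10, a minimum RPKM of 1, rotation, the mean in place of the median, and rescaling of the RPKM sum. For contrasts, adjacent list members were also averaged. Operons were also compared by the mean of their later against their earlier genes and without a pseudocount. Leaving out a replicate was not possible. Dropping short genes was not run, because the deposited files give no gene lengths and none were taken from RefSeq's gene table. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.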

Results

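The transcriptome of E. coli K-12 MG1655, the common laboratory wild type, was measured during exponential growth at 30 °C in minimal medium with glucose as the carbon source. The RNA sequencing belongs to a study of how transcription initiation complexes are organized along the bacterial genome, and it gives the transcript level of each gene in the growth condition used. The 2 libraries form 1 group, and the deposited values are single values for the pair. The coverage profile put the depth at about 24200000 reads by its scaling step and at about 30300000 by its summed coverage, 2 estimates that differ. With 1 value per gene, the variation between the 2 libraries cannot be estimated.

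Most of the listed genes had some signal, but a few stable RNAs held much of it. No background level was estimated, so an RPKM of a few units need not show a transcript of that gene. Of 4205 genes, 3962 (94.2%) had an RPKM of at least 1, 2914 reached 10, 1445 reached 100 and 236 reached 1000. The median of the 4136 protein-coding genes was 40.6 RPKM; the lowest 10% lay at or below 1.63 RPKM and the highest 10% at or above 497 RPKM. The highest value belonged to ssrA (333734 RPKM), the transfer-messenger RNA that rescues stalled ribosomes, which alone made up 15.4% of the RPKM sum. It was followed by cspA (140592 RPKM), the major cold shock protein and RNA chaperone, and ssrS (133291 RPKM), the 6S RNA that binds the housekeeping RNA polymerase holoenzyme. These 3 genes accounted for 28.0% of the RPKM sum, and the 100 highest genes for 70.4%. The next places were taken by rnpB (47419 RPKM), the RNA of ribonuclease P, by cspG (35633 RPKM) and cspE (29003 RPKM), which encode further cold shock family proteins, and by lpp (28382 RPKM), the major outer membrane lipoprotein. The remaining 8 of the 15 highest genes were the ribosomal protein genes rpmI, rpsN, rpsQ, rplV, rpmC and rplP, between 16304 and 27833 RPKM, together with cspB (20586 RPKM) and the porin gene ompA (19516 RPKM).

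The RNA polymerase core genes and 6 of the 7 sigma factor genes were well above the protein-coding median, and the exception was the flagellar sigma factor. Among the core subunits, rpoA reached 7889 RPKM, rpoC 1338 RPKM, rpoB 1258 RPKM and rpoZ 1004 RPKM. The transcript of rpoD, the housekeeping sigma factor, stood at 610 RPKM. The values of rpoS of the general stress response (1694 RPKM), rpoH of the heat shock response (1218 RPKM) and fecI of ferric citrate uptake (1120 RPKM) were 2.78, 2.00 and 1.84 times the rpoD value. The envelope stress factor rpoE (638 RPKM) and the nitrogen-related factor rpoN (546 RPKM) were 1.05 and 0.895 times the rpoD value. The flagellar factor fliA was listed at 1.77 RPKM, a ratio to rpoD of 0.0029. As a list, the sigma and anti-sigma factor genes had a median of 610 RPKM, with 10 of 11 members above the protein-coding median (adjusted p = 0.00039 in the random-list permutation test).

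**Figure D1:**
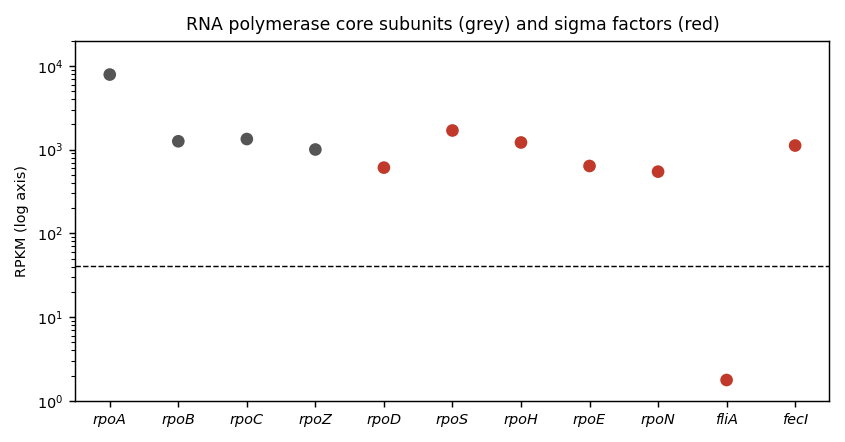
RPKM (log axis) of the 4 RNA polymerase core subunit genes (grey) and the 7 sigma factor genes (red), 1 value per gene for the pair of libraries; the dashed line is the median of protein-coding genes, 40.6 RPKM. All of these genes lie above the line except fliA at 1.77 RPKM.

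The regulons of the alternative sigma factors were each compared with random lists. Genes of the envelope stress factor were high, with a median of 539 RPKM and 16 of 18 members above the protein-coding median (adjusted p = 0.00039, random-list permutation test). Among them skp, a periplasmic chaperone, had 1430 RPKM and rpoH 1218 RPKM, and the lowest were yggN (34.1 RPKM) and yfeK (14.4 RPKM). Heat shock genes had a median of 170 RPKM, with 20 of 22 members above the protein-coding median (permutation test, adjusted p = 0.0093). The protease genes clpP (740 RPKM) and ftsH (739 RPKM) led this list, and the small heat shock protein gene ibpB had 21.3 RPKM. General stress genes under RpoS had a median of 113 RPKM, with 27 of 35 members above the protein-coding median. They were led by the acid chaperone genes hdeA (1291 RPKM) and hdeB (679 RPKM), and the lowest were yciF (8.32 RPKM) and yhbO (6.57 RPKM). Their call (permutation test, adjusted p = 0.030) was lost with rotation (adjusted p = 0.066). Heat shock genes were 1.5-fold above general stress genes in median, a difference that did not pass the permutation test (adjusted p = 0.42).

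Genes under RpoN were low as a list. Their median was 8.48 RPKM, with 30 of 41 members at or below the protein-coding median (permutation test, adjusted p = 0.0079, lost with rotation at an adjusted p of 0.076). The highest were glnA (1806 RPKM), which encodes glutamine synthetase, and hisJ (317 RPKM), a histidine-binding transport protein. The lowest were hycB of formate hydrogenlyase (0.56 RPKM) and atoA of acetoacetate use (0.24 RPKM). The 5 ferric citrate genes under FecI had a median of 69.7 RPKM, from 36.7 RPKM for fecD to 131 RPKM for fecA, and did not differ detectably from random lists (permutation test, adjusted p = 0.685). The fecI transcript at 1120 RPKM stood beside target genes of at most 131 RPKM.

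Flagellar genes were among the lowest of all lists. All 28 genes of the hook and basal body class were below the protein-coding median, at a median of 3.29 RPKM and with flgG (6.18 RPKM) and fliG (5.81 RPKM) highest and fliF (1.10 RPKM) lowest (permutation test, adjusted p = 0.00039; adjusted p = 0.040 with rotation). Of the 21 late flagellar and chemotaxis genes, which FliA transcribes, 18 were at or below the protein-coding median, with a median of 4.47 RPKM (permutation test, adjusted p = 0.0066, lost with rotation at an adjusted p of 0.095). The members above it included flgM (67.0 RPKM), the anti-sigma factor of FliA, and flgN (63.3 RPKM), a chaperone gene, and the chemoreceptor gene tar had 1.56 RPKM. The hook and basal body class was 0.784 times the late class in median, a difference of -0.35 on the log2 scale that did not pass the permutation test (adjusted p = 0.082). With adjacent members averaged, which left 4 values against 7, it was -1.47 on the log2 scale and did not pass either (adjusted p = 0.17, permutation test). Among genes with an RPKM of at least 1, however, it was -0.38 and passed (adjusted p = 0.045, permutation test).

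The ribosomal protein genes made up the 2 highest lists. All 21 genes of the small ribosomal subunit and all 33 of the large subunit lay in the top 10% of protein-coding genes, with medians of 9535 and 9256 RPKM (adjusted p = 0.00039 for each, random-list permutation test). In the small subunit, rpsN (21548 RPKM) and rpsQ (19695 RPKM) were highest and rpsA (4114 RPKM) and rpsU (3842 RPKM) lowest. In the large subunit, rpmI (27833 RPKM) was highest and rplU (1639 RPKM) and rpmA (841 RPKM) lowest. The 54 ribosomal protein genes made up 24.2% of the RPKM sum, and the medians of the subunits differed by 0.04 on the log2 scale (adjusted p = 0.68, permutation test). With adjacent members averaged, the difference was 0.38 and did not pass either (adjusted p = 0.37, permutation test). Translation factors had a median of 1077 RPKM, led by the elongation factor genes fusA (8864 RPKM) and tufA (8337 RPKM). All 22 aminoacyl-tRNA synthetase genes, which charge tRNAs, were above the protein-coding median at a median of 446 RPKM, from cysS (96.9 RPKM) to thrS (1411 RPKM). The small-subunit genes exceeded the synthetase genes 21.3-fold in median (adjusted p = 4.5e-05, permutation test).

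**Figure D2:**
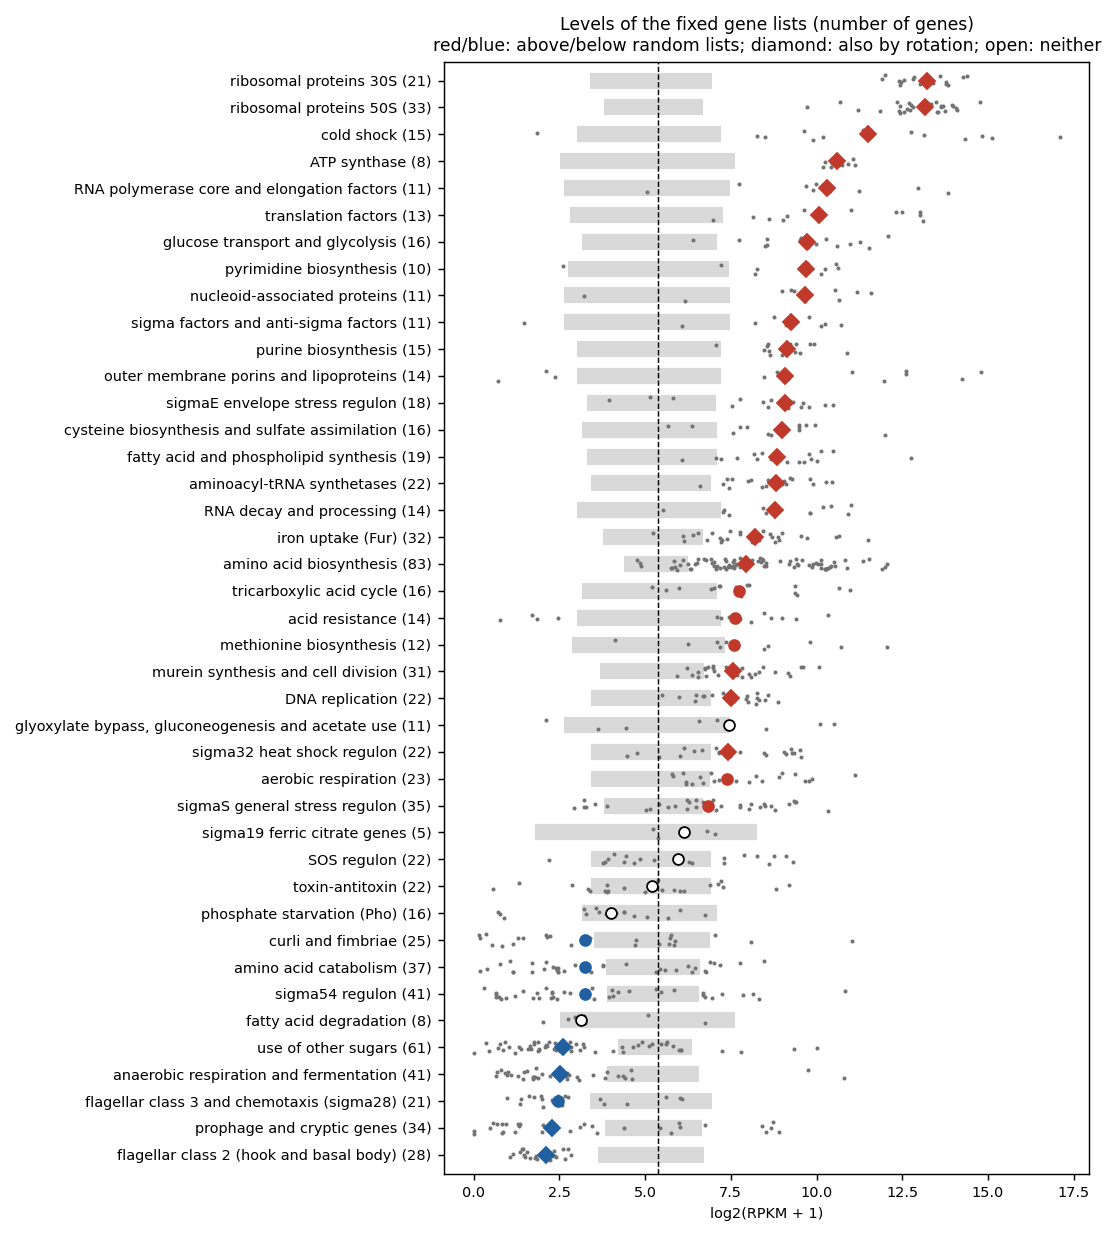
Level of each protein-coding gene (small grey points, log2(RPKM + 1), with vertical scatter for legibility) in the 41 gene lists, with the median of each list as a large symbol and the central range of medians of random lists of the same size as a grey bar. Red and blue medians passed the random-list test above or below, diamonds also passed by rotation, open circles did not pass, and the dashed line is the median of all protein-coding genes, 5.38.

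Of the 41 lists, 27 stood above random lists and 8 below (adjusted p under the threshold in the random-list permutation test), and 22 and 4 of these also passed by rotation. Biosynthetic lists were on the high side. Of 83 amino acid biosynthesis genes, 80 were above the protein-coding median, with a median of 247 RPKM (permutation test, adjusted p = 0.00039). The highest were metE (4274 RPKM), the cobalamin-independent methionine synthase, and cysK (4096 RPKM), a cysteine synthase, and the lowest were tyrA (28.0 RPKM) and lysA (26.1 RPKM). Sulfate assimilation and cysteine genes had a median of 504 RPKM, with all 16 members above the protein-coding median and cysG (50.4 RPKM) lowest. Methionine genes had a median of 193 RPKM, with metR (16.4 RPKM) lowest (permutation test, adjusted p = 0.029, lost with rotation at an adjusted p of 0.092). All 15 purine genes were above the protein-coding median at a median of 568 RPKM, from purT (134 RPKM) to prs (1902 RPKM), which encodes phosphoribosyl pyrophosphate synthetase. Pyrimidine genes had a median of 831 RPKM, led by the aspartate transcarbamylase genes pyrI (1593 RPKM) and pyrB (1511 RPKM), with 9 of 10 members above the protein-coding median. The exception was pyrE, orotate phosphoribosyltransferase, at 5.09 RPKM.

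Amino acid catabolism genes were low, with a median of 8.5 RPKM and 24 of 37 members at or below the protein-coding median (permutation test, adjusted p = 0.0079, lost with rotation at an adjusted p of 0.087). The glutamate decarboxylase genes gadB (355 RPKM) and gadA (218 RPKM) were highest, and the threonine catabolism genes tdcB (0.32 RPKM) and tdcA (0.14 RPKM) lowest. Biosynthesis genes exceeded catabolism genes 26.1-fold in median (difference 4.71 on the log2 scale; adjusted p = 4.5e-05, permutation test). With adjacent members averaged, which counts operon neighbours once, the difference was 3.18 on the log2 scale (adjusted p = 4.5e-05, permutation test), and with a pseudocount of 10 it was 3.80. Genes of fatty acid and phospholipid synthesis had a median of 456 RPKM, led by acpP (6928 RPKM), the acyl carrier protein, and were 52.3-fold above the 8 fatty acid degradation genes (difference 5.71 on the log2 scale, or 4.71 with a pseudocount of 10; adjusted p = 0.00018, exact permutation test; with adjacent members averaged, 5.23 and adjusted p = 0.0023). The degradation list itself, at a median of 7.77 RPKM, did not pass against random lists (permutation test, adjusted p = 0.15). Its highest member was fadL (107 RPKM), an outer membrane transporter, and its lowest was fadH (3.08 RPKM).

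Genes for the uptake and breakdown of glucose were high and those for other sugars low. All 16 glucose transport and glycolysis genes exceeded the protein-coding median, with a median of 845 RPKM. The highest were gapA (4333 RPKM) and eno (2931 RPKM), and the lowest were the minor isoenzyme genes pykA (214 RPKM) and pfkB (82.8 RPKM). Of 61 genes for other sugars, 50 were at or below the protein-coding median, with a median of 5.04 RPKM (permutation test, adjusted p = 0.00039; adjusted p = 0.0025 with rotation). The exceptions were led by the galactitol genes gatY (1034 RPKM) and gatZ (650 RPKM), while gatB of the same operon was listed at 0 and srlB at 0.28 RPKM. The glucose list exceeded the other sugars 140-fold in median (difference 7.13 on the log2 scale, or 5.83 with a pseudocount of 10; adjusted p = 4.5e-05, permutation test).

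Tricarboxylic acid cycle genes had a median of 211 RPKM, with 15 of 16 above the protein-coding median (permutation test, adjusted p = 0.0093, lost with rotation at an adjusted p of 0.092). The highest were lpd (2022 RPKM) and icd (1599 RPKM), and the lowest were the isoenzyme genes acnA (48.2 RPKM) and fumC (35.8 RPKM). The genes of the glyoxylate bypass, gluconeogenesis and acetate use had a median of 172 RPKM and did not pass against random lists (permutation test, adjusted p = 0.0645). In this list, the bypass genes aceA (1443 RPKM) and aceB (1106 RPKM) stood far above acs (11.3 RPKM) and actP (3.33 RPKM) of acetate uptake. The cycle list was 1.22-fold above this list in median, a difference of 0.29 on the log2 scale that did not pass the permutation test (adjusted p = 0.68). With adjacent members averaged it was 2.27 on the log2 scale and did not pass either (adjusted p = 0.13, permutation test).

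All 23 aerobic respiration genes exceeded the protein-coding median, with a median of 167 RPKM (permutation test, adjusted p = 0.0093, lost with rotation at an adjusted p of 0.11). They were led by the cytochrome bo oxidase genes cyoA (2214 RPKM) and cyoB (939 RPKM), and the lowest were the NADH dehydrogenase genes nuoK (55.2 RPKM) and nuoM (54.7 RPKM). The 8 ATP synthase genes, all of the same operon, lay between 1156 RPKM (atpD) and 2242 RPKM (atpE), all in the top 10%. Their adjusted p was 0.00039 in the random-list permutation test and 0.036 with rotation. Of 41 genes of anaerobic respiration and fermentation, 39 were at or below the protein-coding median, with a median of 4.79 RPKM (permutation test, adjusted p = 0.00039; adjusted p = 0.0099 with rotation). The 2 exceptions were pflB (1783 RPKM), pyruvate formate-lyase, and adhE (857 RPKM), the alcohol dehydrogenase of fermentation. Aerobic genes exceeded the anaerobic ones 29.0-fold in median (difference 4.86 on the log2 scale; adjusted p = 4.5e-05, permutation test). With a pseudocount of 10 the difference was 3.58 on the log2 scale. With adjacent members averaged it was 5.84 (adjusted p = 0.027, permutation test), but averaging left only 4 aerobic values against 20 anaerobic ones.

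Cold shock genes formed the highest list after the ribosomal proteins, with a median of 2884 RPKM and 14 of 15 members above the protein-coding median (adjusted p = 0.00039, random-list permutation test). Besides cspA and cspG, the DNA repair gene recA had 303 RPKM and ves 2.60 RPKM. The iron uptake list also held the suf genes, which serve iron-sulfur cluster assembly. Its median was 294 RPKM, with 31 of 32 members above the protein-coding median (permutation test, adjusted p = 0.00039). The highest members were fhuF (2880 RPKM) and exbD (1607 RPKM). Nucleoid protein genes had a median of 804 RPKM, led by hns (3052 RPKM) and fis (2324 RPKM), with stpA at 8.29 RPKM. Porin and lipoprotein genes had a median of 545 RPKM, in which lpp and ompA were highest and the porin genes ompW (3.36 RPKM) and phoE (0.64 RPKM) lowest. The genes of murein synthesis and cell division (median 187 RPKM) and of DNA replication (median 183 RPKM) were all above the protein-coding median, 31 and 22 genes respectively. Prophage and cryptic genes were low, with a median of 3.90 RPKM and 24 of 34 at or below the protein-coding median (permutation test, adjusted p = 0.00039). Here racR (478 RPKM), a prophage repressor gene, was highest, and alpA and emrE were listed at 0. Curli and fimbrial genes were below random lists at a median of 8.56 RPKM (permutation test, adjusted p = 0.036, lost with rotation at an adjusted p of 0.24), although fimA (2113 RPKM), the main type 1 fimbrial subunit, was high. The acid resistance list, at a median of 197 RPKM, was above random lists (permutation test, adjusted p = 0.017, lost with rotation at an adjusted p of 0.11). RNA polymerase and elongation factor genes (median 1258 RPKM) and RNA decay genes (median 442 RPKM) were also above (permutation test, adjusted p = 0.00039 and 0.00068). The SOS, phosphate starvation and toxin-antitoxin lists, at medians of 60.9, 15.1 and 36.0 RPKM, did not pass (permutation test, adjusted p = 0.55, 0.24 and 0.86).

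Levels along operons, whose genes share transcripts, differed in both directions. The last gene was lower than the first in 17 of 26 operons, a share that did not pass the exact sign test (p = 0.17, two-sided). The steepest fall was from rph (102.7 RPKM) to pyrE (5.09 RPKM), a change of -4.09 on the log2 scale; MG1655 is known to carry a frameshift in rph that lowers pyrE expression. The next were from dnaK (534 RPKM) to dnaJ (69.2 RPKM), the chaperone and its partner, and from rpsU (3842 RPKM) to rpoD (610 RPKM), with changes of -2.93 and -2.65. The rpsU operon did not fall steadily, since its middle gene dnaG (246 RPKM) was lower than rpoD. The steepest rises were in the tryptophan operon, from trpE (54.3 RPKM) to trpA (325 RPKM), in the phosphate transport operon, from pstS (8.74 RPKM) to phoU (49.7 RPKM), and in the ATP synthase operon, from atpI (442 RPKM) to atpC (1728 RPKM). These changes were 2.56, 2.38 and 1.96 on the log2 scale. With later genes set against earlier ones, the ATP synthase operon changed by 0.58, since atpI was the lowest of its genes and the others lay between 1156 RPKM (atpD) and 2242 RPKM (atpE), and the other two rises were 2.18 (trpE to trpA) and 2.13 (pstS to phoU).

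**Figure D3:**
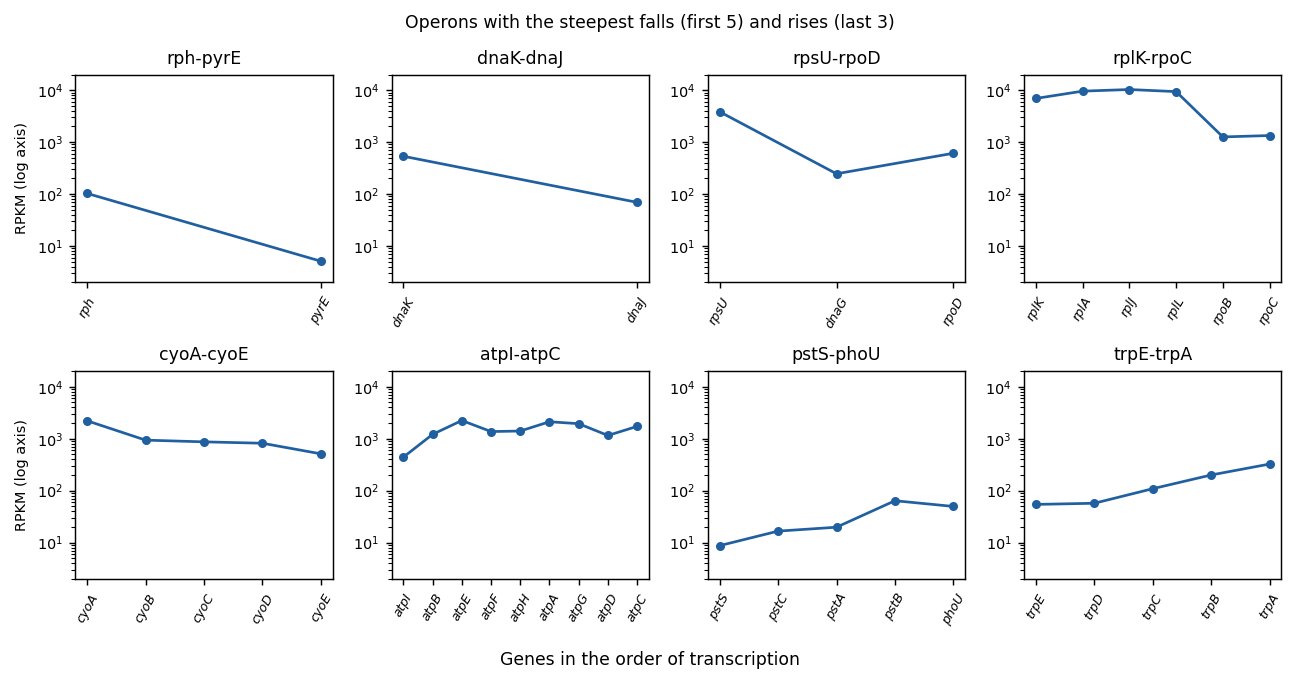
RPKM (log axis) of each gene, in the order of transcription, for the 5 fixed operons with the steepest falls from first to last gene and the 3 with the steepest rises; each point is 1 gene's value for the pair of libraries. In the operon that starts with rplK, the ribosomal protein genes lie between 6930 and 10296 RPKM, and rpoB and rpoC at 1258 and 1338 RPKM.

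The strand-specific coverage profile spread nearly evenly over the strands, with 51% of the signal on the forward strand and 49.0% on the reverse strand. Reads covered 4461462 positions on at least 1 strand, out of positions up to 4639659, and 66.3% of these were covered on both strands. The weaker strand of each position held 1.23% of all signal. In alternatives chosen after seeing the data, this was 0.793% at positions with at least 100 reads and 2.21% without the highest 1% of positions. The share of the weaker strand was 16.6% at positions covered by fewer than 10 reads and 0.0851% at positions covered by 10000 reads or more. Positions were grouped by the same total that divides this share, so a constant background on the weaker strand would also give such a fall. Signal was concentrated: the highest 1% of covered positions held 46.1% of it, and the highest 0.1% held 22.9%. The highest single value was 63208 on the forward strand at position 2753926 of NC_000913 (version not stated in the file), and on the reverse strand 6506 at position 3268290. These positions were not assigned to genes.

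**Figure D4:**
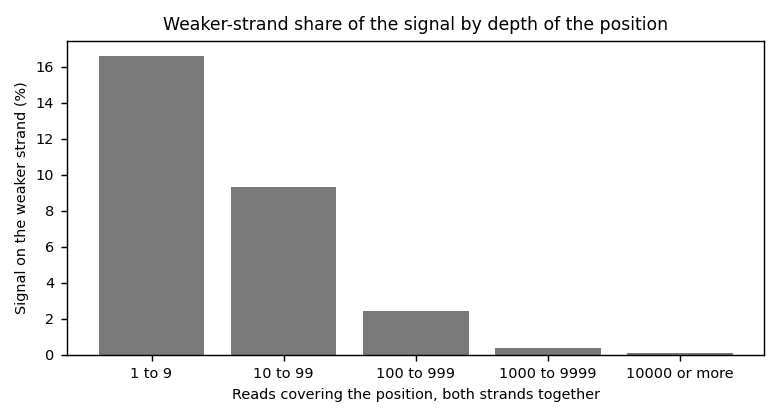
Share of the coverage signal on the weaker strand (%, bars from 0) for positions grouped by the number of reads covering them on both strands together. The share falls from 16.6% at 1 to 9 reads to 0.0851% at 10000 reads or more.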

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

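No paired analysis was possible because the study has 1 group and the files give no value per replicate; for the same reason replicate agreement and the results without each replicate were not computed. With pseudocounts of 0.1 and 10 and with RPKM rescaled to a sum of 1000000, all 35 list calls held. Rotation along the gene order kept 22 of the 27 lists above random lists and 4 of the 8 below, and 9 calls were lost by a test that keeps neighbouring genes together. With a minimum RPKM of 1, the general stress and the curli and fimbriae lists lost their calls (permutation test, adjusted p = 0.058 and 0.37). With means in place of medians, the acid resistance list lost its call (permutation test, adjusted p = 0.16) and the phosphate starvation list gained one below random lists (adjusted p = 0.048). None of the 35 lists called changed its direction under these alternatives. The 5 contrasts that passed also did so under each alternative tried, though their sizes moved: with a pseudocount of 10, the log2 differences of biosynthesis and catabolism, glucose and other sugars, aerobic and anaerobic respiration, and fatty acid synthesis and degradation were 3.80, 5.83, 3.58 and 4.71. Of the others, the difference between the flagellar classes passed only with a minimum RPKM of 1 (-0.38 on the log2 scale, permutation test, adjusted p = 0.045); the cause was not tested. The count of operons with a lower last gene was 17 without a pseudocount and 18 when later genes were set against earlier ones, and 11 of 19 without the operons of ribosomal proteins, an alternative chosen after seeing the data, which tests fewer operons. Chosen likewise, the weaker-strand share of 1.23% was 1.18% at positions with at least 10 reads, 0.793% with at least 100 reads and 2.21% without the highest 1% of positions. The number of detected genes was 2914 at a minimum RPKM of 10 and 4169 above 0. The lowest RPKM values are limited by depth, and no interval was computed, as counts per gene are not in the table. Settings fixed beforehand for antisense signal per gene and for short genes were not run.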

Other observations

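The patterns weighed in this part were noticed in the data, their tests were then fixed before the values they measure were computed, and the genes named here were chosen after their values were seen. Small non-coding RNAs differed widely in level. Of 60 non-coding RNA genes, 13 had at least 1000 RPKM and 2 were above 0 and below 1 RPKM. A further 4 were listed at 0, which in this table need not show a low level. Besides ssrS and rnpB, the highest were tff (9835 RPKM), csrC (8699 RPKM) and ffs (6257 RPKM), the RNA of the signal recognition particle. The CsrA-binding RNA csrB had 2770 RPKM, while csrA itself had 2061 RPKM. The small RNAs glmY (3322 RPKM) and glmZ (2297 RPKM) of amino sugar synthesis, gcvB (2882 RPKM), a regulator of amino acid transport, and ryhB (1365 RPKM), the iron-sparing regulator, were also high. The RpoS-activating RNAs dsrA and arcZ had 0.59 and 4.27 RPKM, and rprA was listed at 0, beside rpoS at 1694 RPKM. How well these libraries kept short RNAs was not tested, so low values of small RNAs may not show low levels.

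The flagellar master regulator genes flhD (23.98 RPKM) and flhC (29.1 RPKM) were above every gene of the hook and basal body class, whose highest member flgG had 6.18 RPKM. Leader peptide genes of attenuated operons differed as well, with thrL at 3770 RPKM beside thrA at 2975 RPKM, ilvL at 1319 RPKM, leuL at 195 RPKM beside leuA at 1286 RPKM, and trpL at 74.8 RPKM beside trpE at 54.3 RPKM. Among vitamin genes, thiC of thiamine synthesis had 2362 RPKM, and bioB of biotin synthesis 277 RPKM.

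In all, 36 genes were listed at exactly 0, among them pdxJ, which encodes an enzyme of pyridoxal phosphate synthesis that cells in minimal medium need, and gatB, which lies between gatC (150 RPKM) and gatA (222 RPKM). A first explanation, that such genes had no transcripts, was predicted to give neighbours like those of genes above 0 and below 1 RPKM. The neighbours of the 35 zero rows with a known place were higher by 2.35 in median log2 level (permutation test, p = 1e-05, the smallest that the permutations can give). The median neighbour level was 3.97 for the zero rows, 1.61 for the low rows and 5.35 for all placed genes. The prediction was not met, but a neighbour's level does not give that of the gene itself. The test therefore cannot exclude genes without transcripts among the zero rows. A second explanation, that reads of a transcribed gene were not credited to it, needs zero rows inside transcribed regions: 20% (7 of 35) had both neighbours above the protein-coding median, against 1.45% (3 of 207) of the low rows (Fisher's exact test, p = 6.6e-05), so it may hold for part of the rows. Over all 4203 placed genes the share was 33.9% (1423 genes), and the zero rows were not tested against it. Besides gatB and pdxJ, the zero rows with both neighbours above the protein-coding median were cydX, pheM, hisL, micF and ohsC. The short length of some of these genes stays open, since gene lengths were not compared. No biological explanation was tested, because the design has 1 group.

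The cold-inducible genes cspA, cspG and cspB were among the 10 highest genes at 30 °C. Reads shared between csp paralogs might raise them together, and then all paralogs would stand at a similar level. Of the other paralogs, cspE (29003 RPKM) and cspI (6924 RPKM), which were not part of the test, stood at 141% and 33.6% of cspB, and the 4 tested were cspC (9019 RPKM), cspF (1090 RPKM), cspD (401 RPKM) and cspH (367 RPKM). Values below 1% of cspB in at least 2 of these 4 would have argued against reads shared between the csp paralogs, and 0 were that low; 3 were below the 10% that sharing was predicted to give, so shared reads and separate transcription cannot be told apart from gene values alone. No sample at another temperature was analysed here, so no biological explanation was tested.

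A further hypothesis was that genes near the replication origin have higher levels through gene dosage. With ribosomal protein and translation factor genes left out, Spearman's rho between level and gene-order distance from mnmG, next to the origin, was -0.0352 across 4069 genes (permutation by rotation, p = 0.59), so the hypothesis was neither borne out nor excluded. Genes are not independent replicates, and with all 4136 protein-coding genes the value was -0.0541 (permutation by rotation, p = 0.084).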
